A study of Arabidopsis thaliana with 6 samples.

How the data were processed

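Leaf mRNA was measured in 6 Arabidopsis thaliana libraries, 2 of wild type (WT, ecotype Columbia-0) and 1 each of 4 mutant genotypes. The leaves were 3 weeks old and came from plants in constant light, and libraries followed the Illumina TruSeq mRNA protocol, per the labels. The mutants carry the alleles nrpe1-11, idn2-1, idnl1-1 with idnl2-1 (the double mutant), or idn2-1 with both idnl alleles (the triple mutant). Groups were taken from the genotype labels. Mutants had no replicates, and nothing in the labels says that the 2 WT libraries came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

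The deposited values are RPKM (reads per kilobase of gene, scaled to the library's total) for 32947 genes in each library. Bowtie is named in the submitters' processing notes, with no version; the TAIR8 gene models are named with the deposited RPKM tables. Handling of multi-mapped reads, duplicates and strand is not given in the sources used here. The values themselves showed how the authors' RPKM were scaled. In every library 100% of the values, times the gene's span from start to stop with introns, were whole multiples of the library's smallest step, within a tolerance of 1e-06 steps. The lowest multiple was 1 and never 0. It was read as 1 read added to each gene, whose origin is not stated, and 1 was taken off wherever read numbers are given. Strand was not used, so overlapping genes, which number 3510, share reads that cannot be assigned to either gene.

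Start and stop positions in the deposited tables were read as counting from 0, so 1 was added to both, and positions are given in TAIR8. In a comparison with TAIR10.1 over the first 300000 bases of each chromosome, the commonest difference between starts was 1 base on chromosomes 1 (22 of 92 genes), 2 (17 of 80) and 4 (33 of 90), but -6 on chromosome 3 and 2 on chromosome 5, where releases may differ, so positions can be off by 1 base. TAIR10.1 served only for symbols, gene class and exon length. Of the gene IDs, 32377 matched it and 570 did not. In that annotation the class pseudogene also holds transposable element genes. Gene symbols follow it except for IDNL1 (there FDM1) and ROS1 (there DML1).

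The RPKM were analysed as log2(RPKM + 1) in R 4.3.3 with limma 3.58.1, with a mean per genotype and an intensity trend in the spread. Fold changes on this scale understate the change of low genes. Genes with at least 1 RPKM in at least 1 library were tested (22362 genes), and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The WT pair gives the fit its only residual degree of freedom (1), so each mutant library was assumed to vary as the WT libraries do. The prior degrees of freedom of this fit were infinite (10.3 with quantile normalization), so each gene's spread was set by the trend over all genes and the p-values do not reflect its own spread. For the class comparison of nrpe1, idn2 and the triple mutant as 1 group against WT, the residual degrees of freedom were 3 and the prior degrees of freedom 8.79. A size rule that needs no model counted genes at least 2-fold above or below each WT library. Among tested genes 3180 had under 10 reads in every library and 1776 stood at the lowest multiple everywhere.

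Read ratios are given with exact 95% binomial intervals; a gene with 0 reads in both WT libraries was set at a floor of 3 counts over the pair. Intervals and floors cover counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for lists, ratios and figures. Each of 20 gene lists was described by its members past the threshold, over all genes and adjusted over the list alone, and by the percentile of its median log2 change among 10000 random lists of the same size matched on mean expression in 20 bins. The lists were the target genes, RdDM machinery, maintenance methylation and heterochromatin, DNA demethylation, genes silenced by DNA methylation, photosynthesis, circadian clock, salicylic acid defence, jasmonate response, heat shock proteins, cold and abscisic acid response, rapid stress and touch response, anthocyanin and flavonoid synthesis, flowering time, floral organ identity, cell division, stomatal lineage and trichomes, senescence and sugar starvation, iron, sulfur and phosphate deficiency, and control genes. A set of transposable element genes named as such in the reference was described likewise. Of the 231 listed genes, 230 were measured; MAF1 was not analysed here. The comparisons, lists, thresholds and the rule for named genes were chosen before the data were examined.

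By that rule, up to 12 genes per direction were named for each mutant against WT among those that passed limma and the size rule, ranked by the difference to the nearer WT library; for the class, genes on the same side of both WT libraries in all 3 mutants were ranked by their smallest difference. Where fewer than 10 passed, the ranking went on among genes meeting only the size rule. For contrasts between mutants and the interaction, 5 genes per direction were named. List members were named where they passed.

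The pseudocount, the filter on low values, the scaling (median of ratios, quantile), the variance trend, the fold and the WT library used were varied. Chosen after seeing the data were voom (limma) on the recovered reads, a correction of abundant genes for a ceiling, a filter of 10 reads, a comparison with the WT library of similar depth by an exact binomial test, and lists of sugar-starvation genes, snoRNA genes and pseudogene-class genes. Similarity between mutants was set against 100 draws of unchanged mutants that share the WT libraries. For shared calls, the genes ranked first by limma p in each direction of such draws were taken in the numbers called in the data, a comparison also chosen after seeing the data.

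The fit was tested on simulated data in which 200 of 22254 genes were changed. For nrpe1 against WT it recovered 51% of genes changed by 1 and 95% of genes changed by 2 on the log2 scale, with 33 false calls; for the class it recovered 81% and 100%, with 16 false calls. With no gene changed among 22234, the false calls were 17 for nrpe1, 4 for the double mutant and 5 for the class. The simulation gave every gene and library the same spread beside counting error, with no batch or ceiling. It thus meets the assumptions of the fit, and these rates need not hold in the data. In the list step, 5% of unshifted and 100% of lists shifted by 0.5 lay outside 95% of random lists. The simulated genes varied independently, while members of a real list can move together, so the rate for unshifted lists need not hold for them.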

Results

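RNA-directed DNA methylation (RdDM) silences transposons and some genes through small RNAs. NRPE1 is the largest subunit of RNA polymerase V, and IDN2 is an RNA-binding protein of the pathway with the relatives IDNL1 and IDNL2. Leaf mRNA levels were compared between WT (n = 2) and 4 mutant genotypes (n = 1 each). Depth, as recovered from the RPKM steps with the added read taken off each gene, was 2737943 reads in WT replicate 1, 3078153 in nrpe1, 2884772 in idn2 and 2793873 in the triple mutant, against 5975802 in WT replicate 2 and 5819494 in the double mutant. A single read in a gene of 2 kb was worth 0.180 RPKM in WT replicate 1 and 0.0832 RPKM in WT replicate 2. The highest RPKM was 474 to 502 in the 4 shallower libraries and 259 and 267 in the 2 deeper ones. The most reads per base of gene span, with the added read, were 1.37 to 1.56 in every library, so the RPKM of the most abundant genes were lower where depth was higher. Whether duplicate reads were removed, and whether the 2 deeper libraries were made as another batch, is not given in the sources used here, so each comparison across the 2 depths carries a batch or depth difference that cannot be told apart from genotype in those libraries.

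The WT libraries differed at least 2-fold in 236 genes, 166 of them higher in replicate 2. Across genes, the Pearson correlation of log2(RPKM + 1) was 0.971 between the WT libraries, 0.986 between WT replicate 2 and the double mutant and 0.982 between WT replicate 1 and the triple mutant, so each of these mutants lay closer to the WT library of its own depth; genes are not independent replicates. The median difference between WT replicates 2 and 1 ran from 0.32 in decile 4 of genes by abundance to -0.21 in the highest decile, while that between the double mutant and WT replicate 2 stayed between -0.01 and 0.03.

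**Figure D1:**
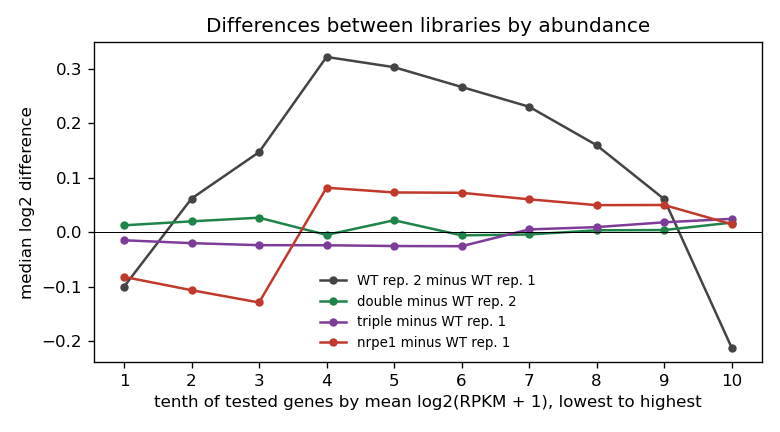
Median difference in log2(RPKM + 1) between pairs of libraries (vertical axis) in each decile of the tested genes by mean log2(RPKM + 1) (horizontal axis, lowest to highest), with a line per pair. WT replicate 2 minus WT replicate 1 lies at -0.21 in the highest decile, while the double mutant minus WT replicate 2 stays between -0.01 and 0.03.

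IDNL1 mRNA was nearly lost in the triple and double mutants, and the mutated NRPE1 and IDN2 genes still gave reads. IDNL1 (AT1G15910, chromosome 1, 5465330 to 5469119) had 4.86 and 6.37 RPKM in WT, 0.187 in the triple and 0.316 in the double mutant, and fell by 2.47 (SE 0.58, limma adjusted p = 0.0107) and by 2.32 (adjusted p = 0.0226). These levels rest on 1 read and 6 reads against 194 in both WT libraries, ratios of 0.0161 (0.000405 to 0.0906) and 0.0463 (0.0168 to 0.103). IDNL2 (AT4G00380, chromosome 4, 167959 to 170974) had 5 and 11 reads against 60, ratios of 0.260 (0.0814 to 0.641) and 0.275 (0.130 to 0.527), and did not pass limma. NRPE1 (AT2G40030, chromosome 2, 16721572 to 16730661) had 2.14 and 3.72 RPKM in WT and 4.92 in the library labelled nrpe1. IDN2 (AT3G48670, chromosome 3, 18041766 to 18045050) had 12.4 RPKM in the library labelled idn2 and 14.8 in the triple mutant, with 118 and 136 reads against 500 in both WT libraries, ratios of 0.713 (0.578 to 0.873) and 0.848 (0.697 to 1.03). Reads over a whole gene span say little about a mutation that leaves part of the transcript, so these genes do not check the labels nrpe1 and idn2, and directions drawn from those libraries rest on the labels.

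**Figure D2:**
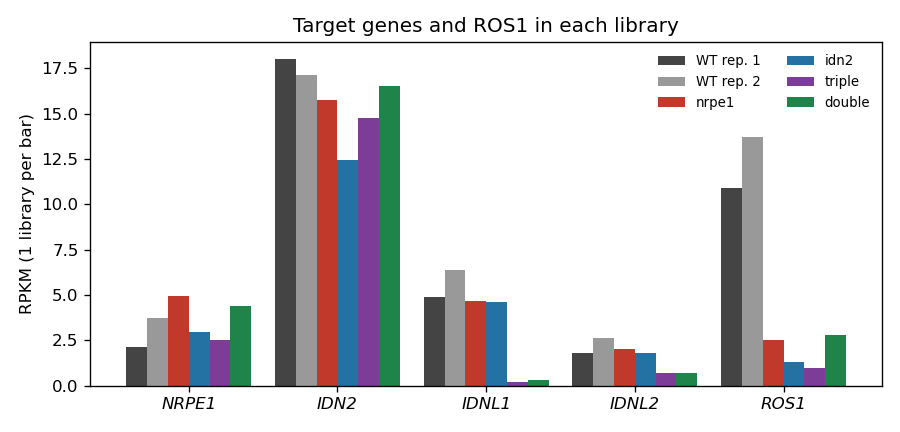
RPKM (vertical axis, from 0) of NRPE1, IDN2, IDNL1, IDNL2 and ROS1 in each of the 6 libraries, a bar per library with no error bar because each is a single library. IDNL1 stands at 0.187 and 0.316 RPKM in the triple and double mutants against 4.86 and 6.37 in WT, and ROS1 at 0.962 to 2.79 RPKM in the mutants against 10.9 and 13.7 in WT.

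The library labelled nrpe1 had the most limma calls of the 4 mutants, 728, of which 579 were falls. The largest falls were in PHI-1 (AT1G35140, also EXL1, a gene of the carbon-starvation response), by 4.38 (SE 0.22, limma adjusted p = 8.82e-86), from 97.0 and 95.9 RPKM in WT to 3.69, and in BT2 (AT3G48360, a BTB and TAZ domain protein), by 4.35 (SE 0.33, adjusted p = 2.75e-36). The ethylene-response-factor family genes AT1G33760, AT5G51190, ERF104 and DREB26 changed by -4.02, -3.81, -3.62 and -3.51. CYP707A3, which breaks down abscisic acid, changed by -3.52, ACS11, of ethylene synthesis, by -3.14, and the mitochondrial carrier DIC2 by -3.30. AT1G50040, AT1G80440 and AT2G27080, which overlaps AT2G27090, changed by -3.65, -3.15 and -3.10.

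The pseudogene-class genes AT4G20365 and AT1G53810 led the rises in the library labelled nrpe1. AT4G20365 (chromosome 4, 10993402 to 10998726, class pseudogene, which also holds transposable element genes) rose by 3.76 and had 218 reads against 0 in both WT libraries, at least 206-fold higher against the floor over the pair, and 0 reads in the other 3 mutants. AT1G53810 rose by 3.66 with 192 reads against 3, a ratio of 181 (61.1 to 886). LTP12, a lipid transfer protein, rose by 3.27 and GRP19, a glycine-rich protein, by 2.85, with 34 and 23 reads against 0 in both WT libraries, at least 32.1-fold and 21.7-fold higher against the floor. FTM1, a desaturase, rose by 3.03. The floral organ list, of tissue other than leaf, lay at a median of 0.59 in the same library, above 99.9% of random lists, with 0 of 7 tested members past the threshold; AP1, PI, SEP3 and AG had 30, 25, 25 and 22 reads, against 7, 5, 7 and 6 in WT replicate 1, of similar depth, and 25, 21, 21 and 20 in the deeper WT replicate 2. AT3G28899 and AT1G33840 each rose by 3.23, RSU1 by 2.95, AT1G67105, a noncoding RNA, by 2.94, AT1G47980 by 2.90 and AT5G26270 by 2.87. PR1, a marker of salicylic acid defence, rose by 2.67 (SE 0.58, adjusted p = 0.000296), from 2.85 and 3.07 RPKM to 24.1. Reads shared between copies of repeated genes make the levels of transposon-like genes uncertain.

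Of 9 genes of the rapid stress and touch response, 8 fell in the library labelled nrpe1 (8 adjusted over the list alone), with a median of -1.64 below all 10000 random lists. They were TCH4, a xyloglucan-modifying enzyme (-2.79), ZAT10 (-2.04), WRKY40 (-2.01), ZAT12 (-1.88), WRKY33 (-1.64), WRKY53 (-1.44), TCH2 (-1.32) and TCH3 (-0.87). Among 10 tested heat shock genes 3 fell (4 adjusted over the list alone), HSP70 by 1.73, HSP90.1 by 1.36 and HSP101 by 1.02. Of 14 jasmonate genes 3 fell (3 adjusted over the list alone), JAZ7 by 2.98, JAZ1 by 1.36 and VSP2 by 0.82. Of 13 tested salicylic acid genes 3 rose (PR1, NIMIN1 by 1.87 and PR2 by 0.92) and 2 fell (CBP60g by 1.74 and WRKY70 by 0.79), the same numbers adjusted over the list alone. Of 11 clock genes 3 fell (3 adjusted over the list alone), RVE8, CCA1 by 0.96 and GI by 0.91. Of 12 cold and abscisic acid genes 1 rose, CBF3 by 2.28, and 2 fell, LTI30 by 0.89 and COR15B by 0.87 (1 and 4 adjusted over the list alone). Of 13 anthocyanin genes 1 fell, UF3GT by 0.88 (1 adjusted over the list alone).

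In all, 149 genes rose and 579 fell (limma, 22362 genes tested), and 134 and 476 met the size rule. The p-values take each gene's spread from the trend over all genes and not from the gene itself. Median-of-ratios scaling gave 1412 calls in place of 728, and the size rule gave 1074 genes without WT replicate 1 and 944 without WT replicate 2. WT replicate 1 stood 2-fold outside both replicate 2 and a mutant in 57 to 108 genes, and replicate 2 outside both replicate 1 and a mutant in 13 to 42. Against pairs of mutants the number reached 421, for replicate 2 against nrpe1 and idn2, which holds changes shared by these mutants. Of 50 called results on named genes, 13 lost their call in at least 1 alternative setting: NIMIN1, PR2, WRKY70, GI, CCA1, HSP101, TCH2, TCH3, COR15B, LTI30, VSP2, UF3GT and ROS1.

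In the library labelled idn2, 316 of 371 calls were falls, led by BT2 and PHI-1. BT2 fell by 4.92 (SE 0.33, limma adjusted p = 2.73e-46), from 56.3 and 55.6 RPKM in WT to 0.881, and PHI-1 by 3.85 (SE 0.22, adjusted p = 5.36e-66). Next came AT4G32480 (-3.74), AT1G23050 (-3.54), AT1G50040 (-3.52), the ethylene response factor ERF6 (-3.44), AT2G01300 (-3.36), the jasmonate repressor JAZ7 (-3.33), AT1G33760 (-3.28), CYP707A3 (-3.27), AT5G19120 (-3.25) and NATA1, an acetyltransferase (-3.03). PR1 rose by 2.57 (SE 0.58, adjusted p = 0.00109), to 22.6 RPKM. The RNA-binding protein gene ARP1 rose by 2.34, the pseudogene-class AT5G35935 by 2.35, MPC by 2.05 (9 reads against 1 in both WT libraries), AT1G60110 by 1.95, ERF15 by 1.93, AT4G12490 by 1.92 and AT5G11090 by 1.44. The snoRNA genes AT2G20721, AT3G47347, AT3G47342 and AT4G39361 rose by 1.81, 1.78, 1.76 and 1.63, on 4, 3, 2 and 6 reads against 2, 1, 0 and 4 in both WT libraries. AT5G52160 fell by 1.75, with 0 reads against 22.

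Of the 9 rapid stress and touch genes 7 fell in the library labelled idn2 (8 adjusted over the list alone), with a median of -1.78, and ZAT10 (-2.24), WRKY33 (-1.89) and TCH4 (-1.84) changed most. Of 10 tested heat shock genes 4 fell (4 adjusted over the list alone), among them HSFA2, a heat shock transcription factor, by 2.70 and HSP70 by 1.86. Of 14 jasmonate genes 3 fell (5 adjusted over the list alone), JAZ7, JAZ1 by 1.53 and VSP1 by 1.41. PR1 alone rose among 13 salicylic acid genes, while CBP60g fell by 1.71 and WRKY70 by 1.01 (1 and 2 adjusted over the list alone). LSU1, of the sulfur-deficiency response, fell by 1.45 as the 1 member past the threshold of 10 (1 adjusted over the list alone). QQS, a starch-related gene silenced by methylation in some plants, fell by 2.08. The totals were 55 genes up and 316 down by limma, and 49 and 333 by the size rule. Median-of-ratios scaling gave 722 calls in place of 371, and the size rule gave 759 genes without WT replicate 1 and 607 without WT replicate 2. Of 42 called results on named genes, 11 lost their call in at least 1 setting: AT2G20721, AT3G47347, AT3G47342, AT4G39361 and LSU1 with voom, and AT1G60110, MPC, AT5G35935, QQS, HSP101 and WRKY70 in others.

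The triple mutant had MRD1, HEI10 and AT5G35935 up and ROS1 down, with far fewer changes in total. MRD1 (AT1G53480, chromosome 1, 19966882 to 19968380) rose by 3.65 (SE 0.60, limma adjusted p = 2.15e-06), with 63 reads against 1 in WT, a ratio of 196 (34.0 to 7883). HEI10 (AT1G53490), a meiotic crossover gene, rose by 2.35, but its span overlaps that of MRD1, so reads of the 2 genes cannot be separated without strand. These 2 genes were also looked at in the other libraries after their values were seen: MRD1 rose in nrpe1 by 2.69 (adjusted p = 0.000423), with 33 reads, and had 7 reads in idn2 (1.14, adjusted p = 0.990), while HEI10 had 52 and 16 reads there against 24 in both WT libraries and did not pass limma (adjusted p = 0.108 in nrpe1). AT5G35935 (chromosome 5, 14100618 to 14107121, class pseudogene) rose by 2.31, with 85 reads against 5, a ratio of 53.0 (21.9 to 167). AT2G04460, of the same class, rose by 2.17. Smaller rises were in AT2G05765 (1.39) and AT3G47347 (1.43), both snoRNA genes with 3 and 2 reads against 3 and 1 in WT, AT3G09870 (1.38), AT4G12490 (1.32), the tRNA gene AT5G61835 (1.25), on 2 reads against 2 in WT, and AT4G22513 (1.13), which overlaps AT4G22510.

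ROS1 (AT2G36490, chromosome 2, 15315100 to 15321351), a DNA glycosylase that removes methylated cytosine, fell by 2.75 in the triple mutant (SE 0.60, adjusted p = 0.00284), with 16 reads against 702 in WT, 14.1-fold lower. AT5G22430 fell by 3.02 and AT4G26290, which overlaps AT4G26288, by 2.73. PYL6, an abscisic acid receptor, fell by 2.32, AT3G61900 by 2.16, DIN10, a raffinose synthase family gene, by 2.03, BBX17 and AT3G14452 each by 1.98 (AT3G14452 with 0 reads against 13 in WT), AT3G15630 by 1.87, AT5G22920 by 1.85 and AT4G27450 by 1.68. By limma 0 of 9 rapid stress and touch genes (median 0.08) and 0 of 10 heat shock genes (median 0.12) passed, also adjusted over the list alone; 0 and 1 had an unadjusted p under 0.05, and voom called 0. VSP1 was the 1 jasmonate gene that fell, by 1.08 (2 adjusted over the list alone). The totals were 16 up and 51 down by limma, and 26 and 133 by the size rule. Median-of-ratios scaling gave 289 calls in place of 67; the size rule gave 459 genes without WT replicate 1 and 345 without WT replicate 2, and 24 up and 65 down against WT replicate 1 alone with an exact binomial test. Of 23 called results on named genes, 12 lost their call in at least 1 setting: IDNL1, HEI10, AT5G35935 and PYL6 with no filter on low values, and AT2G05765, AT3G09870, AT3G14452, AT3G47347, AT4G12490, AT4G22513, AT5G61835 and VSP1 with voom.

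In the double mutant MRD1 rose by 3.96 (SE 0.60, limma adjusted p = 7.39e-08), HEI10 by 2.66 and AT5G35935 by 2.78, the last with 260 reads against 5 in WT. AT4G22485 (2.19), AT4G12490 (1.62), AT3G05727 (1.54, a defensin-like gene), NAC003 (1.97), ERF15 (1.64) and the pseudogene-class AT2G21310 (1.62) rose, as did the snoRNA genes AT3G47347 (2.44), AT2G20721 (1.93) and AT2G05765 (1.90), on 12, 10 and 11 reads. AT5G22430 fell by 3.28, JAZ7 and AT2G05915 each by 2.39, BAM5, a beta-amylase, by 2.05, BT2 by 1.97, AT1G50040 by 1.93, DIN10 by 1.86, AT5G44260 by 1.76, VSP1, a storage protein, by 1.67 and JAL23 by 1.45. AT5G52160 also fell, with 0 reads against 22 in both WT libraries, at least 4.90-fold lower against the floor; it had 0 reads in the triple mutant too, where it changed by -1.74 and did not pass limma (adjusted p = 0.172). JAZ7 and VSP1 were the 2 of 14 jasmonate genes that fell (3 fell and 1 rose adjusted over the list alone), and the rapid stress and heat shock lists had 0 calls by limma and voom, 1 member each at an unadjusted p under 0.05, and medians of -0.20 and -0.19. ROS1 changed by -1.81, with 101 reads against 702, which passed limma adjusted over the list alone (adjusted p = 0.0172) and not over all genes (adjusted p = 0.370).

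In the double mutant 42 genes rose and 35 fell by limma, 54.5% up; the split was 107 and 164 with median-of-ratios scaling, 39.5% up, 47 and 82 with quantile normalization and 36 and 65 with voom. With the spread taken from WT and the other 3 genotypes as 1 group the limma count was 0 in place of 77, with 569 genes at an unadjusted p under 0.05. The size rule gave 45 and 75 genes, and 249 in all without WT replicate 1 and 454 without WT replicate 2. Of 24 called results on named genes, 7 lost their call in at least 1 setting other than that spread: IDNL1, AT2G05915, JAZ7, AT5G52160, AT2G21310, AT2G05765 and AT2G20721.

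The class comparison asked which genes moved alike in nrpe1, idn2 and the triple mutant. AT5G35935 rose by 2.30 (SE 0.25, limma adjusted p = 0.00879) and ROS1 fell by 2.39 (SE 0.30, adjusted p = 0.0119), each in 3 of 3 mutants. Beside ROS1 the falls included AT1G14250 (-2.24), JAZ7 (-2.65), AT2G15880 (-2.53), AT2G05915 (-2.22), AT1G02660 (-2.08), DIN10 (-1.98), PGL1, of the pentose phosphate pathway, whose span overlaps AT1G13690 (-1.90), AT5G44260 (-1.89), XTH18, a cell wall enzyme (-1.88), CYP81F2, of indole glucosinolate synthesis (-1.87), and AT4G17470 (-1.59). AT3G47347 rose by 1.82, ACD6, an ankyrin protein of defence and cell death, by 1.15, BBX29 by 1.14, AT3G45210 by 0.90, AT1G11700 by 0.84 and AT3G14395, which overlaps AT3G14400, by 0.81. MPC (1.70) and AT4G15390 (1.41) met only the size rule. By reads, none of the named calls was particular to the class in its direction. In the double mutant, outside the class, each called fall had fewer reads than WT replicate 2, of similar depth, and each called rise more. For example, AT1G14250 had 86 reads against 320, DIN10 279 against 1138, BBX29 242 against 104 and ACD6 989 against 543. In all 7 genes rose and 52 fell, and 1694 had an unadjusted p under 0.05. The count depends on single libraries: it was 0 without WT replicate 2 (1049 at an unadjusted p under 0.05), 115 without WT replicate 1 (111 up and 4 down, 5 shared with the 59), 347 without nrpe1, 120 without idn2 and 993 without the triple mutant, and 0 with quantile normalization (1711 at an unadjusted p under 0.05); voom gave 67. Each of the 19 called results on named genes lost its call with quantile normalization.

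The triple mutant was compared with idn2 to see what loss of IDNL1 and IDNL2 adds, and with the double mutant to see what loss of IDN2 adds. HSFA2 was higher in the triple mutant than in the library labelled idn2 by 3.69, BT2 by 3.67, PHI-1 by 3.52, CYP707A3 by 3.36 and AT4G32480 by 2.98, all past the threshold. PR1 (-3.61), AT4G26290 (-2.78), AT3G61900 (-2.63), the microRNA gene MIR169m (-2.39, on 0 reads against 7) and ARP1 (-2.34) were lower. Of the 9 rapid stress and touch genes 7 were higher (8 adjusted over the list alone), with a median of 1.53 above all random lists, and 4 of 10 heat shock genes were (4 adjusted over the list alone). In total 149 genes were higher and 33 lower, 81.9% higher; this share ranged from 72.5% with median-of-ratios scaling to 91.8% with voom. Of 22 called results on named genes, 8 lost their call in at least 1 setting: MIR169m, ARP1, JAZ1, HSP101, TCH2, TCH3, WRKY53 and WRKY70.

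Against the double mutant, 13 genes were lower and 0 higher by limma, with 507 at an unadjusted p under 0.05; voom gave 0 in either direction. They included AT4G26290 (-3.01), the noncoding RNA AT1G15405 (-1.99) and the snoRNA genes AT2G20721 (-2.15), AT3G47348 (-1.83) and AT4G39363 (-1.79), on 0, 1 and 1 reads against 10, 15 and 15, and each of these 5 lost its call with voom. The median of all genes was -0.13 in this contrast and -0.00416 after median-of-ratios scaling, under which 10 genes were higher and 33 lower (23.3% higher); 20% were higher with quantile normalization. The libraries differ in depth, and no contrast of the same depth could be made. The interaction, which asks whether the triple mutant departs from the sum of the idn2 and double mutant changes on the log scale, was past the threshold in 179 genes, 129 above the sum and 50 below it. Depth does not cancel in the interaction either. Nor can a level fall below 0 on this scale. Where idn2 and the double mutant both fell strongly, a value above the sum can follow in part from that floor.

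Changes of nrpe1 and idn2 were correlated across genes at Pearson r = 0.641, where unchanged mutants sharing the same WT libraries gave 0.333; the covariance was 0.111 against a simulated 0.0426. They shared 253 falls, where unchanged mutants sharing the same WT libraries gave 42.5 between top-ranked lists of the same lengths and independent lists 8.18, and 36 rises, against 4.20 and 0.366. For the other 5 pairs r was 0.361 (nrpe1 and triple), 0.478 (idn2 and triple), 0.228 (nrpe1 and double), 0.253 (idn2 and double) and 0.182 (triple and double), and the covariances of the last 3 pairs lay below the simulated value. Shared falls numbered 25, 29, 27, 34 and 19 in these 5 pairs, against 10.5, 7.18, 7.93, 4.78 and 1.34 between unchanged mutants and 1.32, 0.721, 0.906, 0.495 and 0.0798 for independent lists. Shared rises numbered 8, 6, 21, 19 and 10, against 1.74, 0.890, 3.83, 1.96 and 0.720 between unchanged mutants. With each mutant set against a different WT library, nrpe1 and idn2 gave 0.305 and 0.363, and pairs with the double mutant changed sign. The simulated values carry the depth difference of the WT pair, and part of any excess may come from the shared controls, which cannot be halved into groups of 2. In the draws each library varied independently. In the data nrpe1, idn2 and the triple mutant have the depth of WT replicate 1, and the double mutant that of replicate 2. Shared depth could raise similarity among the former and lower it in pairs with the double mutant, so the simulated values are not an exact baseline.

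ROS1 was the 1 gene of the RdDM, maintenance methylation and demethylation lists past the threshold over all genes. In each of the 4 comparisons 0 of 28 tested RdDM machinery genes and 0 of 16 maintenance methylation and heterochromatin genes passed limma, and 0 adjusted over the list alone; 1 of them, of the maintenance list in nrpe1, had an unadjusted p under 0.05, and voom called 0. Of the 7 demethylation genes only ROS1 fell, by 1.91 in nrpe1 and by 2.52 in idn2 as well as in the triple mutant, with 48 and 23 reads against 702 in WT, 5.17-fold and 10.1-fold lower. Among 5 tested genes known to be silenced by DNA methylation, 0 passed in nrpe1 over all genes by limma (3 at an unadjusted p under 0.05, 1 by voom), while 2 did adjusted over the list alone: SDC (1.66) and MRU1 (0.62). The list median in nrpe1 was 0.84, above 99.99% of random lists. With 5 genes this median is the value of QQS alone, which did not pass (limma adjusted p = 0.947). QQS had 19 reads in nrpe1 against 7 and 22 in WT replicates 1 and 2, and changed by -2.08 in idn2. The set of 41 tested transposable element genes had 0 calls by limma in any mutant, also adjusted over the list alone, 4 members in nrpe1 and 0 in the others at an unadjusted p under 0.05, and 1 call by voom, in nrpe1. The set comes from the 97 genes named as transposons in the reference. It leaves out pseudogene-class genes not named so, such as AT4G20365, and does not stand for transposons in general. Its medians were 0.16 in nrpe1, 0.01 in idn2, 0.08 in the triple and 0.03 in the double mutant; the triple mutant's was -0.0816 without WT replicate 1 and -0.0157 without WT replicate 2.

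**Figure D3:**
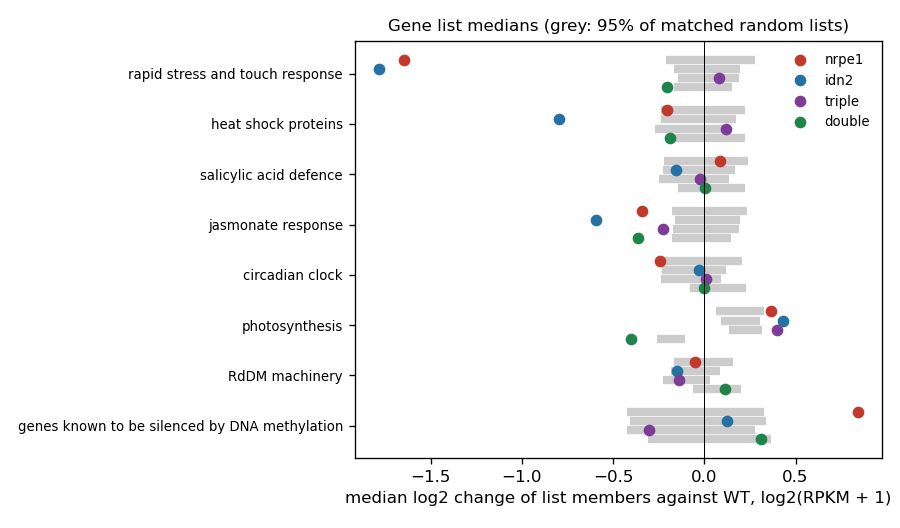
Median difference in log2(RPKM + 1) to WT (axis) of 8 gene lists in each of the 4 mutants, with grey bands holding 95% of random lists matched on size and mean expression. The rapid stress and touch list lies at -1.64 in nrpe1 and -1.78 in idn2, against 0.08 in the triple and -0.20 in the double mutant.

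The measure was near its ceiling for photosynthesis genes. RCA, the Rubisco activase gene, had 2157 to 2398 reads in the 6 libraries, and over the 19 genes of the list the median ratio of reads between WT replicates 2 and 1 was 1.16, against 2.18 for the totals. Limma and voom gave 0 calls among the 19, with 0 at an unadjusted p under 0.05, which says nothing of whether these genes changed. Their medians were 0.36 in nrpe1, 0.43 in idn2, 0.40 in the triple and -0.40 in the double mutant; against the WT library of similar depth these were -0.0756 in nrpe1, 0.00766 in idn2, -0.0180 in the triple and 0.0387 in the double mutant. Floral organ genes, which mark tissue other than leaf, had 0 calls among 7 tested by limma and voom, 2 members in nrpe1 and 0 in the others at an unadjusted p under 0.05, and medians of 0.59 in nrpe1, -0.14 in idn2, -0.48 in the triple and -0.54 in the double mutant. No member passed in any mutant among the flowering time (4 tested), cell division (7), stomatal lineage and trichome (11), and control (10) lists, over all genes or adjusted over the list alone, by limma or, over all genes, by voom, and 0 had an unadjusted p under 0.05. In the control list the median ratio of reads between WT replicates 2 and 1 was 1.78, also below the 2.18 of the totals. Its 0 calls therefore carry part of the limit given for photosynthesis genes. Of 3 tested senescence and sugar starvation genes 0 passed over all genes; SEN1, a dark-induced gene, passed adjusted over the list alone in idn2 (-1.46), the triple (-1.98) and the double mutant (-1.71). Lists not named for a mutant above had 0 calls by limma over all genes in it, and 0 to 4 members at an unadjusted p under 0.05; adjusted over the list alone these included SDI1 in nrpe1 (-1.66), LSU1 in the triple mutant (-0.81), LUX in idn2 (-1.01) and PRR9 in the double mutant (0.72). Of 80 list medians, 26 lay outside 95% of random lists.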

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

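The interaction contrast was planned; the tests of explanations for it were chosen only after the result was seen. The change from loss of IDN2, as labelled, differed between plants with and without the idnl1 and idnl2 mutations in 179 genes past the limma threshold. The double mutant is deeper than idn2 and the triple mutant, so a depth or batch difference does not cancel in this contrast. The largest positive departures were in BT2 (5.64), PHI-1 (4.46), AT1G50040 (4.30), JAZ7 (4.08) and AT4G32480 (4.05). On the scale used a level cannot fall below 0, so the sum of 2 large falls can lie below what is possible. A positive departure then follows in part from the scale. JAZ7 and BT2 had 0 and 5 reads in idn2 against 27 and 363 in WT replicate 1, and both also fell in the double mutant. The number of the 179 genes affected was not counted. The largest negative ones were in AT2G20721 (-3.96), MIR169m (-3.86), AT3G47348 (-3.30), AT4G26290 (-3.06) and ERF15 (-2.97). AT2G20721, MIR169m and AT3G47348 rest on 0, 0 and 1 reads in the triple mutant, 4, 7 and 10 in idn2 and 10, 13 and 15 in the double mutant. They had 0, 0 and 1 reads in WT replicate 1 and 2, 7 and 13 in WT replicate 2. Of 20 called results on named genes, 5 lost their call in at least 1 setting: AT3G47348, JAZ1, TCH3, TCH4 and WRKY53. Each rests on 1 library per mutant, and a contrast of 4 genotype means has a higher error than the other contrasts of the same fit.

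The genes called in the library labelled nrpe1 moved alike in that labelled idn2 and less in the triple mutant. Over these 728 genes the median change in the nrpe1 direction was 0.69 in idn2 (683 of the same sign), 0.19 in the triple mutant (526) and 0.21 in the double mutant (529), where unchanged mutants sharing the WT libraries gave 0.26 (584 of the same sign). Falls shared with nrpe1 numbered 25 in the triple and 27 in the double mutant, where the highest draw of unchanged mutants gave 18 and 13. The draws leave out depth shared between libraries, so they are not an exact baseline here either. Depth is argued against for the difference between idn2 and the triple mutant, which are of similar depth, since its median over these genes was 0.44 (0.41 to 0.51, over genes and not libraries). The triple mutant, as labelled, carries the same idn2 mutation. Of these genes, 140 passed limma in the triple mutant against idn2 opposite to the nrpe1 direction and 3 in it. These numbers restate the pattern, with 1 library against 1. They therefore cannot decide whether loss of IDN2 without an interaction of the genotypes is the whole cause. Handling or time of harvest cannot be told apart from genotype with 1 library per mutant. The rapid stress and touch list lay at percentile 0 of random lists in the nrpe1 and idn2 libraries. That is part of the pattern itself and would be seen under either cause, so it decides nothing. An effect of IDN2 loss that depends on IDNL1 and IDNL2 stays open.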

How the results depend on the processing

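The alternatives with voom, recovered-read filters, ceiling correction and same-depth binomial tests were chosen after seeing the data. No paired analysis was possible because each mutant has 1 library and shares only the number 1 with WT. Without either WT library limma has no residual degrees of freedom for a single mutant against WT; the size rule, list medians, correlations and the limma class count were recomputed. Of the results other than counts and summaries, alternatives set in advance left 1778 the same, 147 weaker, 4 stronger, 42 moved and 3 reversed, and added ones left 620 the same and 37 weaker. Of counts and summaries, those set in advance left 58 the same, 49 moved and 5 reversed, and added ones left 32 the same and 4 moved. Of 205 called results on named genes, 125 kept their call in all settings and 80 lost it in at least 1, 43 with no variance trend, 33 with voom and 25 with quantile normalization. The cause was not tested for any change below unless a smaller set of samples or genes shows it. Low genes rest on few reads, and the RPKM of the most abundant genes were lower where depth was higher.

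Median-of-ratios scaling moved the limma counts to 1412 (nrpe1), 722 (idn2), 289 (triple), 271 (double), 451 (triple against idn2), 43 (triple against double), 479 (interaction) and 16 (class). Quantile normalization gave 129 for the double mutant, 5 for triple against double and 0 for the class. Without a variance trend triple against double had 20 and the class 1. A pseudocount of 0.25 gave 36 for the class. A minimum of 10 reads gave 108 for the triple mutant. Voom gave 97 for triple against idn2 and 0 for triple against double. The double mutant had 0 with the spread from WT and 3 genotypes as 1 group, and all 4 mutants against WT gave 26. Leaving out each library in turn, the class count ranged from 0 to 993.

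The size rule gave 940, 617, 403 and 234 genes for nrpe1, idn2, the triple and the double mutant at a pseudocount of 0.25, and 219, 129, 27 and 27 at 3-fold. Leaving out each WT library gave 944 to 1074, 607 to 759, 345 to 459 and 249 to 454. The exact binomial test against the WT library of similar depth gave 89 for the triple mutant.

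With the first mutant of a pair against WT replicate 1 and the second against replicate 2, and then the other way round, r was 0.305 and 0.363 (nrpe1 and idn2), 0.0291 and 0.123 (nrpe1 and triple), 0.283 and -0.229 (nrpe1 and double), 0.0931 and 0.157 (idn2 and triple), 0.352 and -0.279 (idn2 and double) and 0.338 and -0.378 (triple and double). At a pseudocount of 0.25 nrpe1 and double gave 0.206.

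Leaving out each WT library, the transposable element median ranged from 0.0954 to 0.120 in nrpe1, -0.117 to 0.0215 in idn2, -0.0816 to -0.0157 in the triple and 0.0137 to 0.0848 in the double mutant. It changed sign under both in the triple mutant and without WT replicate 1 in idn2. The photosynthesis median ranged from -0.0756 to 0.822 in nrpe1, -0.0180 to 0.847 in the triple and -0.835 to 0.0387 in the double mutant, and reversed in each against the WT library of similar depth. In idn2 it ranged from 0.00766 to 0.893.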

Other observations

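The tests below were chosen only after the result was seen, except the count of transposon-like genes between mutants and WT. Several genes of the sugar-starvation response fell in each of the 4 mutants. Of 14 tested members of a list put together after seeing the data, 8 fell in nrpe1, 8 in idn2, 6 in the triple and 7 in the double mutant (9, 11, 10 and 11 adjusted over the list alone), with medians of -1.09, -1.25, -1.04 and -1.08. STP1, a monosaccharide transporter, was at 62.1 and 63.1 RPKM in WT and at 27.0 to 28.7 in the 4 mutants. BXL1, a beta-xylosidase, was at 52.3 and 50.8 RPKM in WT and at 17.0 to 24.8 in the mutants. The class II trehalose-phosphate synthase genes TPS8 and TPS11 fell in each mutant, TPS11 by 1.94 in nrpe1 and by 1.24 in the double mutant. The list was chosen with BT2, PHI-1 and DIN10 already seen to fall, so it is not independent evidence. In the senescence and sugar starvation list fixed in advance, SEN1 changed by -0.93 in nrpe1, while SAG13 and ASN1 changed by 1.07 and 0.53. ASN1 changed by -0.17 in idn2, -0.35 in the triple and -0.22 in the double mutant, and SAG13 by -0.07, -0.43 and 0.66. No change of SAG13 or ASN1 passed limma, also adjusted over the list alone.

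The 71 tested snoRNA genes, whose RNA has no poly(A) tail as a rule, had medians of 0.29, 0.35 and 0.37 in nrpe1, idn2 and the triple mutant and -0.33 in the deeper double mutant, with 9, 7, 2 and 4 members that rose and 1, 1, 2 and 0 that fell. The sign of the median followed depth.

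ROS1 was lower and AT5G35935 higher in all 4 mutant libraries than in both WT libraries. The smallest of the 8 changes against the WT library of similar depth was 1.76. For nrpe1, idn2 and the triple mutant this restates the choice of the genes, which were ranked by their smallest difference to either WT library. The double mutant was not used in that ranking. There ROS1 had 101 reads and AT5G35935 260, against 514 and 2 in WT replicate 2, which argues against depth for that library. Counting error is argued against, since 8 of the 8 exact intervals of the read ratios excluded 1, though the genes were chosen for large changes. Growth or harvest differences between WT and mutant plants were not tested. Loss of RdDM at these loci, for which methylation was not analysed here, was not tested either and stays open.

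Pseudogene-class genes made up 8.05% of the genes that rose in the library labelled nrpe1 against 1.17% of tested genes, an odds ratio of 7.70 (Fisher's exact test, adjusted p = 1.99e-06 over 10 tests). The share was 12.5% of the rises in the triple mutant (2 of 16 genes, odds ratio 12.1, adjusted p = 0.0736), 4.76% in the double mutant (adjusted p = 0.174) and 1.82% in idn2 (adjusted p = 0.796). The base of these tests depends on the filter. A gene under 1 RPKM in both WT libraries was tested only if it reached 1 RPKM in a mutant. Of 3890 genes of the class among the 32947 measured, 262 were tested. The odds ratios therefore cannot show that the class rose more often than other genes. Genes of this class with at least 10 reads in a mutant and at most 1 read in each WT library numbered 7 in nrpe1, 0 in idn2, 0 in the triple and 1 in the double mutant, against 0 and 4 between the WT libraries. In nrpe1 these 7 were 0.189% of 3707 such genes, against 0.315% (19 of 6030) of protein-coding genes (Fisher's exact test, two-sided p = 0.313), so the class was not shown to be switched on more often than other genes. The lowest number over the mutants, 0, met neither outcome set for counting error of low genes over all 4, so that test decides nothing. For nrpe1 alone counting error is argued against, since 7 such genes stand against 0.00022 expected. They include AT4G20365, AT5G42645, AT5G27947 and AT5G27925 with 218, 29, 25 and 24 reads. Reads shared between copies were not tested.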
